A study of Mus musculus with 8 samples.

How the data were processed

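Preadipocytes isolated from the white adipose tissue of wildtype and Irf3-knockout mice were differentiated in culture, and RNA was taken at days 3, 5, 7 and 9. Total RNA was extracted with TRIzol and labelled as biotinylated cRNA for Illumina bead arrays. There was 1 array for each genotype and day, 8 arrays in all, so no condition had a replicate. Whether the 4 days of a genotype came from 1 animal or culture is not given in the sources used here, nor are the strain, the sex, the slide of each array or the part of Irf3 that was deleted.

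The deposited table that is not normalized holds a mean bead intensity per probe on a linear scale, with no background subtracted, for 25697 probes. Beside each intensity it gives a detection p-value (p_value), which the authors deposited from the array's own negative controls. The mean raw intensity ran from 638 on the wildtype day 3 array to 1026 on the knockout day 7 array, and the median from 135.2 to 212.1. Between 12224 and 13414 probes per array, 47.6% to 52.2%, had a detection p under 0.05. The number of arrays limits the precision of the values.

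The deposited matrix of processed values is also an intensity on a linear scale. Its lowest value is 20, which 48.2% to 50.5% of the probes of each array held. Its wildtype day 3 column equalled the raw signal minus 111.8 to 111.9, and the other 7 columns were scaled non-linearly, with Spearman correlations with the raw signal of 0.999 to 1 among values above the floor. The authors' normalization is not given in the sources used here. In that matrix 11109 probes stood at 20 on all 8 arrays, and 676 of these had a detection p under 0.05 on at least 2 arrays. None of the 676 had a detection p under 0.05 on the wildtype day 3 array. For these reasons the raw table was the main source and the matrix an alternative.

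The raw intensities were processed with limma 3.58.1 in R 4.3.3. The function neqc corrected the background by normexp with the detection p-values, added an offset of 16, quantile-normalized the arrays and took log2. Probes with a detection p under 0.05 on at least 2 of the 8 arrays were kept, 14232 in all. The probe table paired 23978 probes with 1 gene symbol each, none with several, and 1719 with none. Of the 23978 probes, 23962 were matched through their gene identifiers to the names used with assembly GRCm38.p6, whether or not the symbol changed. A gene was represented by its probe with the highest mean over the 8 arrays, which gave 9758 genes, 2601 of them with over 1 probe. The genome build of the array is not stated, so the reference served only for names and for the order of genes, in which 9754 of the 9758 tested genes were found.

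The genotype comparison fitted genotype with day as a factor, so that the 4 daily differences between knockout and wildtype were the repeats and their spread the error, with 3 residual degrees of freedom. A true change of the difference with day counts as error in this fit. The change with day was a slope per day fitted over both genotypes with genotype as a term, with 5 residual degrees of freedom. The difference in slope between the genotypes was the interaction term of a further fit, with 4. Tests were two-sided moderated tests of limma with Benjamini-Hochberg adjustment over the genes, and an adjusted p under 0.05 made a call. A descriptive count took genes at least 2-fold apart in the same direction on all 4 days. On a single day, 1 array stood against 1, so the differences had no test, and each list's median was placed among 10000 random lists of the same size matched on mean expression.

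Gene lists for pathways, for cell types that such cultures could hold, and for the neighbours of Irf3 were fixed before the data were examined. The 25 lists with at least 5 measured members were tested with limma's camera at a preset inter-gene correlation of 0.01. Camera with an estimated correlation and limma's fry were alternatives. The lymphocyte list had 2 measured members, the nerve sheath list 4 and the sex chromosome list 2, and these 3 lists were not tested.

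Single genes were named by a rule that was also fixed before the data were examined. Irf3 and its neighbour Bcl2l12 came ahead of the rest. For genotype, the rule took the 12 genes higher and the 12 lower with the largest mean difference among those called and with 1 sign on all 4 days. For day it took the 10 steepest in each direction among those called with the same sign in each genotype. For the difference in slope it took the 5 and 5 with the smallest p if none was called. In each list, up to 4 members with the smallest p were named. Names of clones and of predicted genes were skipped. Errors of log2 values are standard errors from the fits.

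The steps were tested on simulated data with the gene means and spread of these arrays, 9758 genes of which 200 changed. For genotype, 88 of 100 genes changed by 1 on the log2 scale and 100 of 100 changed by 2 were called, and 6.93% of calls were false. For the change with day, 88 of 100 slopes of 0.25 per day and 100 of 100 of 0.5 were called, and 6.47% of calls were false. For the difference in slope, 10 of 100 differences of 0.25 per day and 94 of 100 of 0.5 were called, and 3.70% of calls were false. A list of 30 shifted genes passed camera with the preset correlation in 20 of 20 draws for each of the 3 comparisons. With an estimated correlation it passed in 18 of 20 draws for genotype and in 20 of 20 for each of the slopes. The simulated noise was independent between genes. In the real genotype comparison the estimated correlation was, for example, 0.30 for the interferon-stimulated list and 0.56 for the respiratory chain list. The draws therefore do not test either form of camera at such correlations.

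Alternatives changed 1 choice at a time: no background correction, scaling to 1 median in place of quantiles, the deposited processed values, no filter, a filter of detection p under 0.01 on at least 4 arrays, the mean of a gene's probes, a trended and robust variance prior, other forms of the day term, each genotype alone, and leaving out each day or array. Those chosen after seeing the data were the 2-fold count without each day, the mean of the macrophage list as a covariate, and the processed values without the genes that stood at 20 on all arrays. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.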

Results

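The 8 arrays followed wildtype and Irf3-knockout preadipocytes at days 3, 5, 7 and 9 of adipocyte differentiation, 4 arrays per genotype and 1 per genotype and day. Irf3 encodes a transcription factor that is activated below sensors of viral nucleic acids and bacterial products and drives interferon and interferon-stimulated genes. The series asks how its loss bears on the differentiation of fat cells. Across the 9758 tested genes the day of culture and the genotype together ordered the arrays. The main axis of variation, 55.9% of the variance, ran in wildtype from -55.9 on day 3 through -30.9 and 0.92 to 14.2 on day 9, and in knockout from -35.4 through 13.6 and 44.2 to 49.4. On this axis the knockout array of day 5 lay close to the wildtype array of day 9. On the next axis, 18.8% of the variance, these arrays stood apart, at 6.34 and -25.8. The Pearson correlation across genes, which are not independent replicates, was 0.962 between the knockout and wildtype arrays of day 5 and 0.977 between the knockout array of day 5 and the wildtype array of day 7. For the knockout array of day 3 it went the other way, 0.976 with wildtype day 3 and 0.969 with wildtype day 5. The knockout array of day 7 gave 0.959 with wildtype day 7 and 0.964 with wildtype day 9.

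Irf3 transcript was read by 3 probes, all above background on all 8 arrays. The probe with the highest signal, ILMN_2664319, gave a log2 intensity of 11.23 in wildtype and 10.73 in knockout on average, a difference of -0.50 ± 0.17 (SE, 4 days; adjusted p = 0.166). The daily differences of Irf3 were -0.25, -0.49, -1.01 and -0.26. The other probes of Irf3 differed by -0.62 and -0.31 on average. Which part of Irf3 was deleted is not given in the sources used here, so the level of Irf3 on these arrays cannot check the genotype labels. Bcl2l12, the gene beside Irf3, fell by 1.67 on the log2 scale in knockout (SE 0.25, adjusted p = 0.0148) and was above background on all 4 wildtype arrays and 1 knockout array. Its call was lost without day 5 (adjusted p = 0.0577) or day 7 (0.0594), and without background correction Bcl2l12 stood at -0.61.

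Knockout cultures carried less transcript of interferon-stimulated genes and more of macrophage and fat cell genes than wildtype cultures at the same days. Isg15, a ubiquitin-like modifier made in response to interferon, was 14.7-fold lower in knockout (log2 difference -3.88 ± 0.47, lower on 4 of 4 days). Irf7, a transcription factor that amplifies the interferon response, was 10.1-fold lower (-3.33 ± 0.20), and above background on 3 of 4 knockout arrays. Mrc1, the mannose receptor of macrophages, was 6.87-fold higher in knockout (2.78 ± 0.23), and Adgre1, the macrophage marker F4/80, was 6.21-fold higher (2.63 ± 0.21). Fabp5, a fatty acid-binding protein, rose by a log2 difference of 1.79 ± 0.17, and Pnpla2, the triglyceride lipase of fat cells, by 1.58 ± 0.26, a call that Pnpla2 lost without day 7 or day 9.

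Limma called 473 of 9758 genes for genotype, 267 higher and 206 lower in knockout, each with the same sign on all 4 days, and 149 genes were at least 2-fold apart in the same direction on each of the 4 days, 79 higher and 70 lower. The count of 473 was 1082 without day 3, 199 without day 5, 182 without day 7 and 161 without day 9. It was 771 with a trended and robust variance prior, 115 with no day term (25 higher, 90 lower) and 93 on the deposited processed values (375 without the genes at their floor on all arrays), and the count of 149 was 340 without day 3 and 67 without background correction (27 higher, 40 lower).

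Among the 12 genes named for the largest rise, 3 are in the macrophage list, Mrc1, Adgre1 and Fcgr2b. Cbr2, a carbonyl reductase, rose by 3.04 ± 0.40 (adjusted p = 0.00859), Fcgr2b, an inhibitory receptor for IgG, by 2.61 ± 0.27, Trem2, a lipid-sensing receptor of macrophages, by 2.53 ± 0.19, and Lilra6, a leukocyte receptor, by 2.63 ± 0.45. The apolipoproteins Apoc1 and Apoe rose by 3.46 ± 0.63 and 2.58 ± 0.42, most on day 3, when they differed by 5.95 and 4.29. Abhd1 rose most, by 3.79 ± 0.28, and its 3 probes gave 3.79, 3.58 and 4.01. Atp10d, a phospholipid flippase, rose by 2.62 ± 0.22 and Rnase1, a secreted ribonuclease, by 2.54 ± 0.24. Cbr2, Lilra6 and Rnase1 were above background on 2, 1 and 3 of the wildtype arrays. Zfp985 was at least 2.99-fold higher in knockout and not above background on any wildtype array.

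Among the 12 genes named for the largest fall, 5 are in the type I interferon list. Beside Isg15 and Irf7 these were Usp18, which removes Isg15 from proteins, at -3.34 ± 0.34, Rsad2, the antiviral protein viperin, at -3.30 ± 0.36, and Oas2, which makes the activator of RNase L, at -3.04 ± 0.40. Plk1, a kinase of mitosis, also fell (-4.67 ± 0.22, adjusted p = 0.000337), but it was above background on 1 of 4 knockout arrays, so the size of its fall rests on background values. Plk1 was read by 1 probe, and no other gene of the cell cycle list was called for genotype. Psmd8, a subunit of the proteasome, was 19.1-fold lower (-4.26 ± 0.14, adjusted p = 0.000116). Lars2, the mitochondrial leucyl-tRNA synthetase, was at least 9.61-fold lower and Prkag2, a subunit of the AMP-activated kinase, at least 7.84-fold lower, and neither was above background on any knockout array. The lysosomal protease Ctsc (-3.61 ± 0.26), Nudt6 (-3.33 ± 0.15) and the milk casein Csn3 (-3.17 ± 0.17) also fell, and were above background on 3, 2 and 3 knockout arrays. Of the 24 genes named, Apoc1, Apoe and Lilra6 lost their call without day 5 (adjusted p = 0.105, 0.0763 and 0.0836) or without day 9 (0.0521, 0.0606 and 0.112), Lilra6 also without day 7 (0.0699), and Cbr2 without day 9 (0.0514). On the deposited processed values 13 of the 24 lost it. Isg15 (-3.89), Usp18 (-3.28), Rsad2 (-3.40), Oas2 (-3.14) and Ctsc (-3.80) lost it with differences of similar size, and Lilra6, Rnase1 and Zfp985 are constant there.

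**Figure D1:**
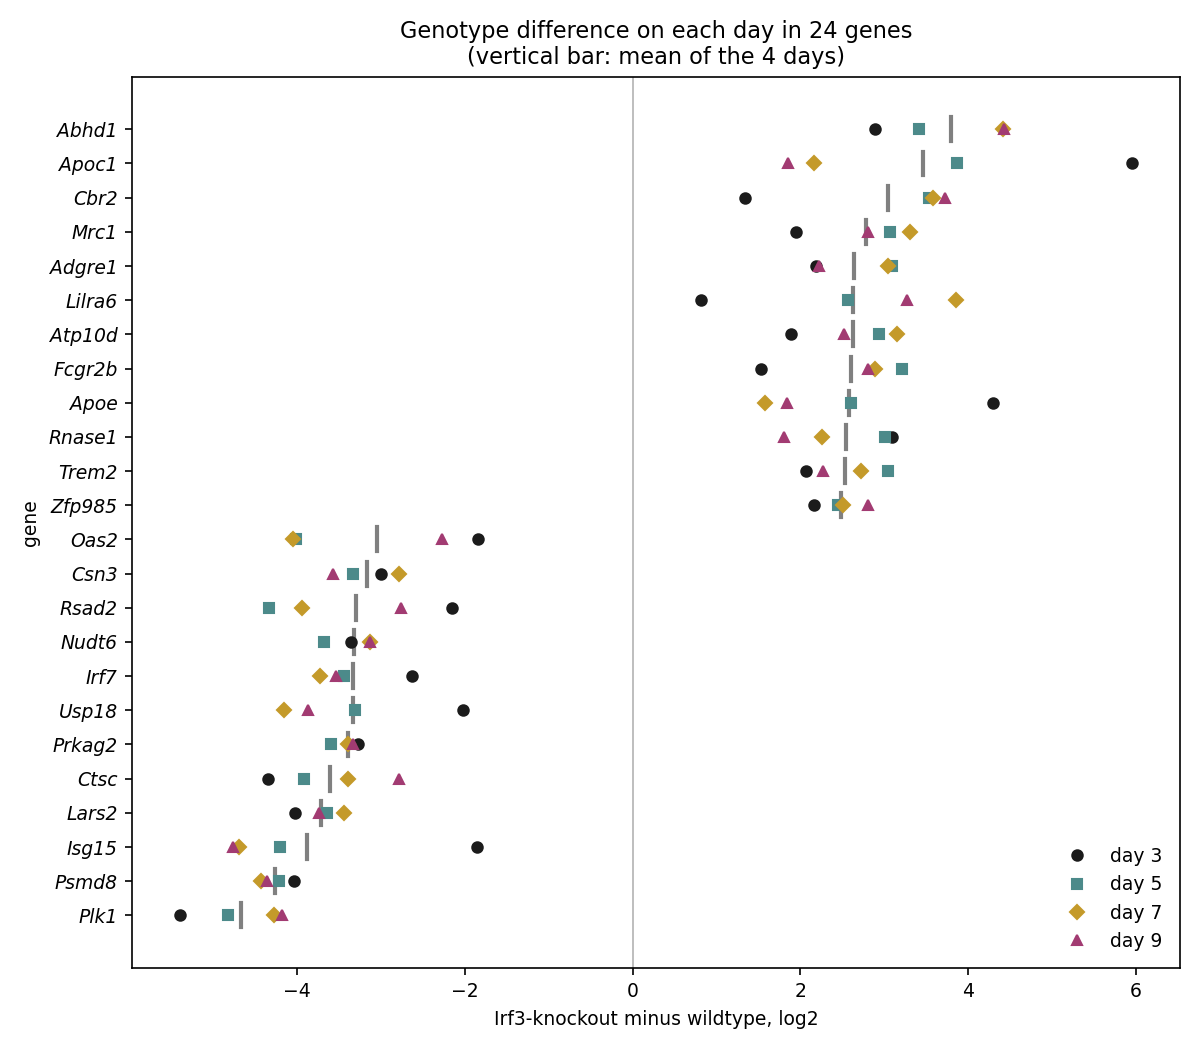
Log2 difference between the knockout and the wildtype array of the same day (horizontal axis) in the 24 genes named for genotype, with 1 symbol per day and a vertical bar at the mean of the 4 days. Psmd8 lay between -4.43 and -4.04 on the 4 days, whereas Isg15 moved from -1.85 on day 3 to -4.76 on day 9 and Apoc1 from 5.95 on day 3 to 1.85 on day 9.

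The 25 gene lists were then tested against all other genes with camera at its preset correlation, and 15 passed, 6 with a median above 0 and 9 below. None of the 15 passed with an estimated correlation, where the lowest adjusted p was 0.302 and 3 of the 25 lists had an unadjusted p under 0.05. Fry, which asks whether a list's genes move one way on balance, called 8 lists. Of the 15 it called fatty acid oxidation, interferon-stimulated, interferon-gamma-type, NF-kB, macrophage and mesothelial genes, and beyond them the brown and beige adipocyte list (adjusted p = 0.00929) and the pattern recognition list (0.0464). It did not call the mature adipocyte list (0.0559) or fatty acid and triglyceride synthesis (0.0577).

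All 38 measured type I interferon-stimulated genes had a difference below 0, and 29 of them fell, with a median of -1.19 (camera adjusted p = 6.8e-33; adjusted p = 0.302 with an estimated correlation). Adjusted over the list alone, 36 fell. Irf7, the helicase sensor Dhx58 (-1.82 ± 0.13), the oligoadenylate synthetase-like gene Oasl1 (-2.12 ± 0.15) and the antiviral GTPase Mx2 (-2.93 ± 0.23) had the smallest p. Of the 27 interferon-gamma-type and antigen presentation genes 8 fell and 2 rose, with a median of -0.52 (adjusted p = 4.2e-05; adjusted p = 0.302 with an estimated correlation), and adjusted over the list alone 12 fell and 4 rose. The GTPases Ifi47 (-1.52 ± 0.15) and Igtp (-1.78 ± 0.18) and the chemokine Cxcl9 (-2.55 ± 0.31) fell, and H2-Ab1, a chain of the class II molecules of antigen-presenting cells, rose by 1.13 ± 0.15. The list of pattern recognition and Irf3 pathway components did not pass (adjusted p = 0.291), although 3 of its 19 members fell, adjusted over all genes and adjusted over the list alone: Irf7, Irf9 (-1.11 ± 0.14), a transcription factor of the interferon response, and the RNA sensor Ddx58 (-1.23 ± 0.16). Of 30 NF-kB and inflammatory genes 3 fell and 2 rose, with a median of -0.30 (adjusted p = 0.0140; adjusted p = 0.302 with an estimated correlation), and adjusted over the list alone 5 fell and 2 rose. The neutrophil chemokines Cxcl5 (-1.50 ± 0.18) and Cxcl1 (-1.30 ± 0.20) fell, and Ccl9 (1.06 ± 0.18) and Tnf (0.97 ± 0.18) rose.

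All 24 measured macrophage and monocyte markers had a difference above 0, and 16 rose, with a median of 1.77 (adjusted p = 2.9e-22; adjusted p = 0.302 with an estimated correlation); adjusted over the list alone, 21 rose. Fcgr3, a receptor for IgG, rose by 2.39 ± 0.13 and Laptm5, a lysosomal protein of blood cells, by 1.94 ± 0.14, with Adgre1 and Mrc1 beside them. On the single days the list's median difference was 1.58, 2.13, 1.97 and 1.67, each at percentile 100 among random lists. The rise of macrophage markers accompanied every other change between the genotypes described here.

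The fat cell lists were higher in knockout, in the cultures whose macrophage list was higher by a median of 1.77. Of 22 mature adipocyte markers 5 rose and none fell, with a median of 1.53 (adjusted p = 1.8e-11; adjusted p = 0.302 with an estimated correlation), and adjusted over the list alone 18 rose. Fabp5, Pnpla2, the glycerol channel Aqp7 (1.53 ± 0.27) and Dgat2, which completes triglyceride synthesis (1.54 ± 0.29), had the smallest p. Of 21 genes of fatty acid and triglyceride synthesis 6 rose, with a median of 1.09 (adjusted p = 6.9e-10; adjusted p = 0.302 with an estimated correlation), and adjusted over the list alone 14 rose. Among these were Lpin1, a phosphatidate phosphatase (1.37 ± 0.15), Gpam, the mitochondrial glycerol-phosphate acyltransferase (1.09 ± 0.17), Dgat1 (1.03 ± 0.19) and Acss2, an acetyl-CoA synthetase (0.94 ± 0.17). Of 18 adipogenic transcription factors, the list as a whole did not pass (adjusted p = 0.299), but Pparg, the main regulator of fat cell differentiation, rose by 1.12 ± 0.22 and Mlxipl, which responds to glucose, by 1.58 ± 0.30. Both lost their call without day 5, day 7 or day 9. Adjusted over the list alone, 5 of the 18 rose. Fatty acid oxidation passed with a median of 0.54 over 22 genes (adjusted p = 2.1e-07; adjusted p = 0.302 with an estimated correlation). None of these 22 was called over all genes and 11 rose adjusted over the list alone; Acadm stood at 0.71 ± 0.16 (adjusted p = 0.0625). The respiratory chain and TCA cycle list passed with a median of 0.37 over 43 genes (adjusted p = 4.2e-10; adjusted p = 0.342 with an estimated correlation). In it Ndufb5 rose by 0.83 ± 0.16, 42 of the 43 estimates were above 0, and none rose adjusted over the list alone.

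The single days had 1 array per genotype and no test, and the slope of the mature adipocyte list did not differ between genotypes by camera (median difference 0.0058 per day, adjusted p = 0.717). That result rested on single arrays: without the knockout array of day 3 the median difference was -0.41 (camera adjusted p = 1.0e-06). The median difference of the mature adipocyte markers was 0.37 on day 3, 2.45 on day 5, 1.33 on day 7 and 1.02 on day 9, at percentiles of 99.95, 100, 100 and 100 among random lists. That of fatty acid and triglyceride synthesis was 0.18, 1.29, 1.56 and 1.14. Adipoq, the adipokine adiponectin, read 6.31 in wildtype and 9.26 in knockout on day 3, 11.63 and 14.05 on day 5, and 14.01 and 14.41 on day 9, and was not called over the 4 days (adjusted p = 0.106). The interferon-stimulated list stood at -1.01, -1.27, -1.48 and -1.47. On the single days 533, 879, 1051 and 906 genes were at least 2-fold apart, and without background correction 150, 301, 442 and 353.

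Of the markers of other cell types, the mesothelial, endothelial and preadipocyte lists were lower in knockout over the 4 days and the skeletal muscle list was higher. Of 9 mesothelial and epithelial markers 4 fell, with a median of -1.20 (adjusted p = 7.4e-06; adjusted p = 0.302 with an estimated correlation), and adjusted over the list alone 8 fell and 1 rose. The keratins Krt18 (-1.20 ± 0.13), Krt8 (-1.70 ± 0.27) and Krt7 (-1.02 ± 0.18) and the tight-junction protein Cldn4 (-1.69 ± 0.23) made up the 4. All 15 endothelial markers had a difference below 0 and 1 fell, Flt1, a receptor for VEGF, at -0.76 ± 0.14; the median was -0.40 (adjusted p = 7.2e-05; adjusted p = 0.303 with an estimated correlation), and 3 fell adjusted over the list alone. On the single days the endothelial median was -0.58, -0.62, -0.59 and -0.12, with 7 of 15 above 0 on day 9. The 23 preadipocyte and progenitor markers had a median of -0.32 (adjusted p = 0.00168; adjusted p = 0.303 with an estimated correlation). The only member called was Dlk1, a marker of uncommitted preadipocytes, which rose by 0.88 ± 0.16 against its list and lost its call without day 5, 7 or 9, and adjusted over the list alone 1 rose and 1 fell. The single-day medians of this list were 0.042, -0.28, -0.36 and -0.44, with 12 of 23 above 0 on day 3. Skeletal muscle markers had a median of 0.42 over 11 genes (adjusted p = 0.00256; adjusted p = 0.342 with an estimated correlation), but the list did not pass without day 3 (0.25, adjusted p = 0.102). On the single days its median was 1.42, 0.07, 0.01 and 0.30, with 11 of 11 members above 0 on day 3 (percentile 100). Myl1, a myosin light chain, rose by 1.08 ± 0.17, the only one also when adjusted over the list alone, and lost its call without day 5 or 9.

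Camera also called 3 further lists. Red blood cell and mast cell markers had a median of -0.72 over 5 genes, none called and 2 lower adjusted over the list alone (adjusted p = 0.00441; adjusted p = 0.342 with an estimated correlation), and the list did not pass with no filter (-0.32, adjusted p = 0.0540). In the extracellular matrix list Tnc, a matrix glycoprotein, fell by 0.91 (SE 0.18), with a median of -0.10 over 34 genes and 6 lower adjusted over the list alone (adjusted p = 0.0145; adjusted p = 0.342 with an estimated correlation), and the list did not pass without day 9 (adjusted p = 0.0853). In the myofibroblast list Cald1, an actin-binding protein, fell by 0.81 (SE 0.16), with a median of -0.26 over 12 genes and 3 lower adjusted over the list alone (adjusted p = 0.0159; adjusted p = 0.302 with an estimated correlation), and the list did not pass without day 7 (adjusted p = 0.0715).

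Cell cycle genes did not differ as a list (adjusted p = 0.842, median of 0.00089 over 25 genes), with single-day medians of -0.26, -0.14, 0.16 and 0.17 that went opposite ways. Plk1 was the only member called, adjusted over all genes and adjusted over the list alone. Brown and beige adipocyte markers (adjusted p = 0.0885, with single-day medians of 0.06, -0.0059, 0.84 and 0.95), insulin and AKT signalling (0.0510), oxidative stress and NRF2 targets (0.0609), glycolysis (0.653), cholesterol synthesis (0.369), the unfolded protein response (0.842) and the neighbours of Irf3 (0.155) did not pass camera. In these lists Cox7a1, a cytochrome oxidase subunit of muscle and brown fat (1.47 ± 0.21), the growth factor Igf2 (1.28 ± 0.24), catalase, Cat (1.73 ± 0.27), Pgk1 (0.68 ± 0.13), and among the neighbours Dhdh (0.92 ± 0.18) and Cd37 (0.94 ± 0.20) rose. Of the 28 neighbours 19 had an estimate below 0, and Bcl2l12 fell. The median and the mean of the glycolysis, cell cycle and unfolded protein lists had opposite signs.

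**Figure D2:**
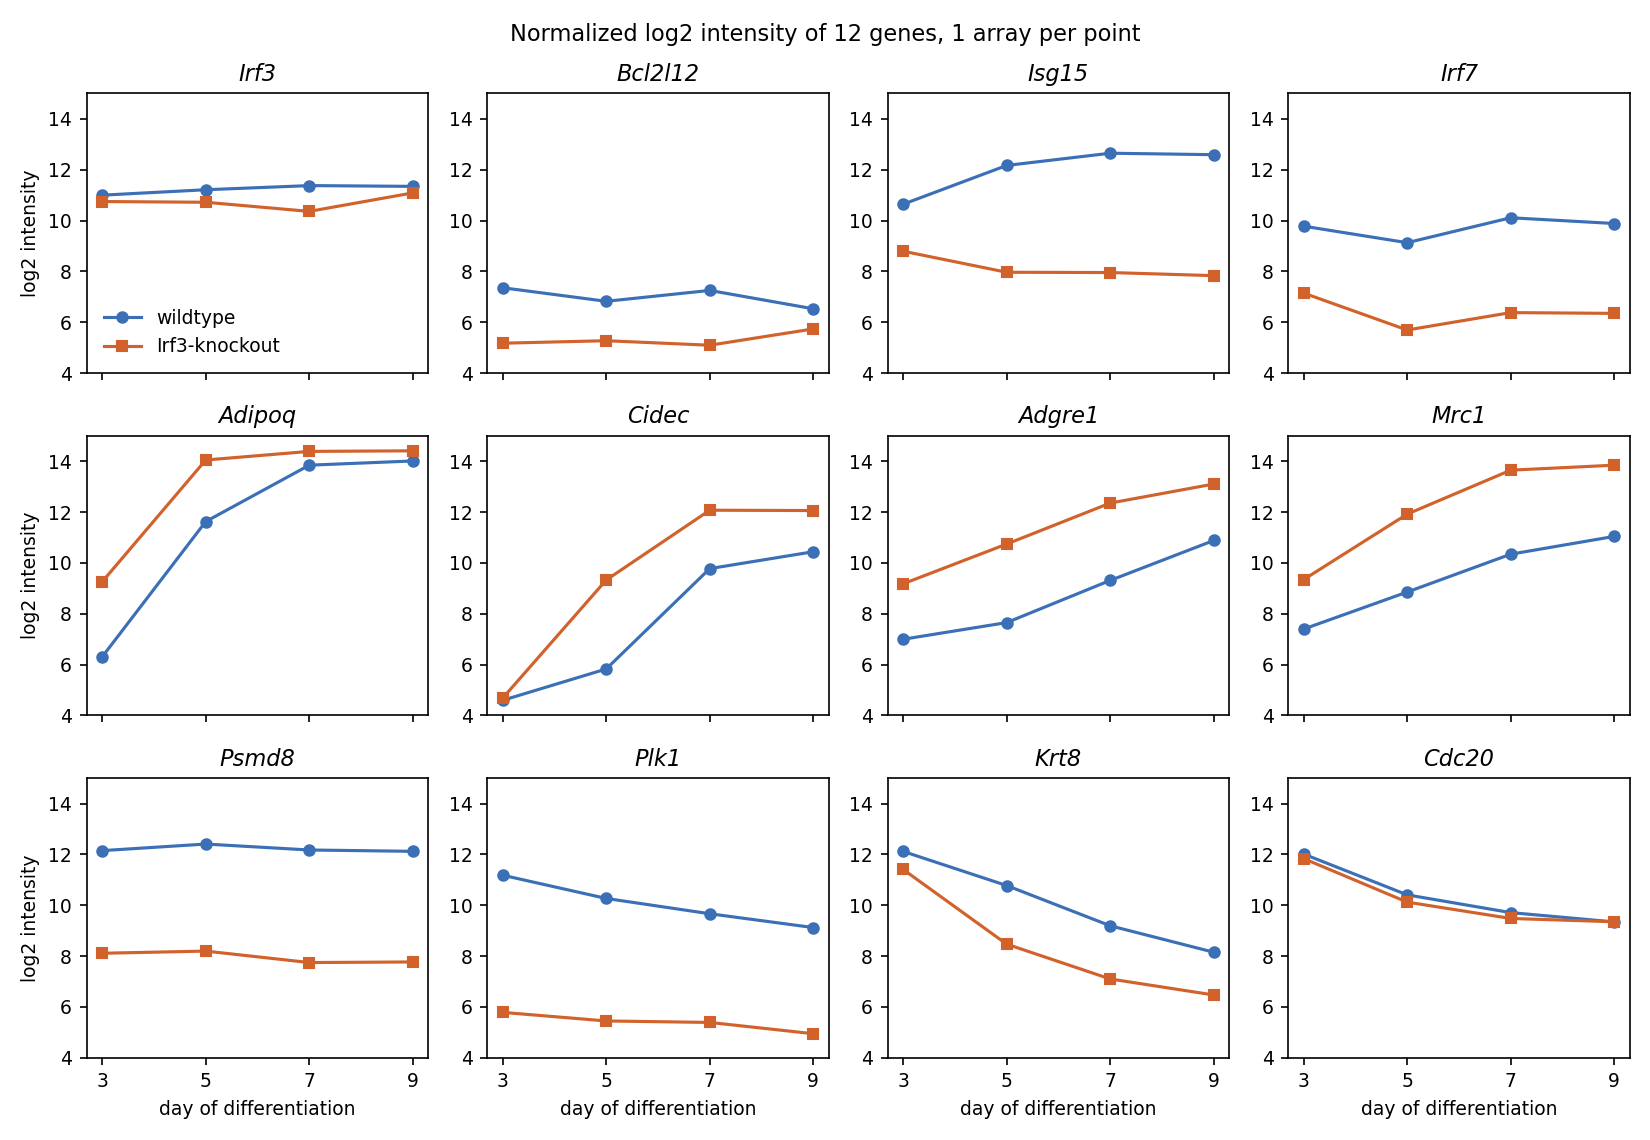
Normalized log2 intensity (vertical axis) by day of differentiation (horizontal axis) in 12 genes, with 1 array per point, wildtype in blue and knockout in orange. Psmd8 stayed near 12.2 in wildtype and 8.0 in knockout at all days, Adipoq was higher in knockout mainly on days 3 and 5, and Cdc20 followed nearly the same course in both genotypes.

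Over the days both genotypes gained transcripts of fat cells and macrophages and lost those of dividing, muscle and epithelial cells. Thrsp, a lipogenic protein of fat cells, rose by 1.37 ± 0.20 log2 per day and went from background on both day 3 arrays (4.84 in wildtype, 5.00 in knockout) to 11.86 and 13.51 on day 9. Cidec, which coats lipid droplets, rose by 1.16 ± 0.15 per day, and Adipoq by 1.03 ± 0.21. Krt8 fell by 0.74 per day (SE 0.07), 21.8-fold from day 3 to day 9, and Cdc20, an activator of the anaphase-promoting complex, by 0.42 per day (SE 0.06).

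Limma called 1638 genes for the change with day, 833 rising and 805 falling, all 1638 with the same sign in each genotype alone. The count was 408 without the knockout array of day 3, 916 without the wildtype array of day 9, 187 in wildtype and 253 in knockout arrays alone. Across all tested genes, which are not independent, the slopes of the genotypes had a Pearson correlation of 0.727.

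Beside Thrsp, Cidec and Adipoq, the steepest rises were in Orm1, an acute-phase plasma protein (1.24 ± 0.20 per day), Adig, a membrane protein of fat cells (1.24 ± 0.19), the major urinary proteins Mup2 (1.13 ± 0.19) and Mup6 (1.06 ± 0.19), Reg1 (0.93 ± 0.24), Cox8b, a cytochrome oxidase subunit of brown fat and muscle (0.93 ± 0.13), and Tmem45b (0.90 ± 0.10). The steepest falls beside Krt8 were in Cldn4 (-0.76 ± 0.08), Cldn11 (-0.74 ± 0.16), Krt18 (-0.73 ± 0.08), cardiac actin Actc1 (-0.73 ± 0.10), Krt14 (-0.72 ± 0.08), Wfdc2 (-0.69 ± 0.10), Chrna1, a subunit of the muscle acetylcholine receptor (-0.64 ± 0.09), Krt17 (-0.61 ± 0.05) and Cxcl1 (-0.58 ± 0.09). Thrsp, Cidec, Orm1, Adig and Tmem45b were at background on both day 3 arrays, and Cldn4, Cldn11, Krt18, Actc1, Wfdc2 and Chrna1 on the knockout array of day 9, and Cox8b on the wildtype arrays of days 3 and 5, so their slopes rest in part on background values. Another probe of Wfdc2, with a mean log2 intensity of 5.54 against 7.35, differed between genotypes by -0.25 where the named one differed by -1.61. These are genotype differences and do not bear on the slope of Wfdc2. Of these 20 genes 14 lost their call without the arrays of day 3, where Adipoq stood at 0.34 per day (adjusted p = 0.241) and Reg1 at 0.14 (0.324), and without day 7 Reg1 and Cldn11 did. Tmem45b, Cldn4, Krt8, Actc1, Krt14 and Krt17 kept it without day 3.

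Of 25 lists 11 passed camera for the change with day, 7 upward and 4 downward, and none passed with an estimated correlation (lowest adjusted p = 0.118, with 2 lists at an unadjusted p under 0.05). Fry called 9 lists, 8 of these 11 and the brown and beige list, and not the respiratory chain, fatty acid oxidation or interferon-stimulated lists. Of 24 macrophage markers 20 rose, and 22 adjusted over the list alone, with a median of 0.48 per day (adjusted p = 1.8e-21; adjusted p = 0.118 with an estimated correlation). Coro1a, an actin-binding protein of leukocytes, rose by 0.56 ± 0.04, Laptm5 by 0.52 ± 0.04 and Tyrobp, a signalling adaptor of myeloid cells, by 0.59 ± 0.04. Of 22 mature adipocyte markers 15 rose, and 17 adjusted over the list alone, with a median of 0.62 (adjusted p = 1.7e-10; adjusted p = 0.324 with an estimated correlation). Among them were Fabp5 (0.52 ± 0.07) and the insulin-responsive glucose transporter Slc2a4 (0.73 ± 0.11). Of 21 genes of fatty acid and triglyceride synthesis 16 rose, and 18 adjusted over the list alone, with a median of 0.43 (adjusted p = 1.5e-11; adjusted p = 0.324 with an estimated correlation). Fatty acid synthase, Fasn, rose by 0.63 ± 0.10 and Mlxipl by 0.73 ± 0.10.

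Small upward medians passed in 4 further lists. The respiratory chain list had 7 of 43 genes rising with a median of 0.04 per day (adjusted p = 6.5e-05; adjusted p = 0.553 with an estimated correlation), with Pdhb, a subunit of pyruvate dehydrogenase, at 0.37 ± 0.07, and also 7 adjusted over the list alone. Fatty acid oxidation had 2 of 22 rising, also 2 adjusted over the list alone (median 0.08, adjusted p = 0.00272; adjusted p = 0.491 with an estimated correlation). The interferon-gamma-type list had 6 of 27 rising and 8 adjusted over the list alone (median 0.08, adjusted p = 0.000693; adjusted p = 0.324 with an estimated correlation), H2-Ab1 by 0.18 ± 0.03. The interferon-stimulated list had 4 of 38 rising and 3 adjusted over the list alone (median 0.06, adjusted p = 0.000855; adjusted p = 0.491 with an estimated correlation), among them Rtp4 (0.21 ± 0.04), and it did not pass without the wildtype array of day 3 (adjusted p = 0.0508).

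All 25 cell cycle genes had a slope below 0 and 21 fell, 25 adjusted over the list alone, with a median of -0.26 per day (adjusted p = 3.5e-13; adjusted p = 0.324 with an estimated correlation). Cdc20 had the smallest p, followed by Birc5, which protects dividing cells (-0.32 ± 0.05), and the nucleotide enzymes Tk1 (-0.30 ± 0.05) and Tyms (-0.27 ± 0.04). Of 11 skeletal muscle markers 8 fell, 9 adjusted over the list alone, with a median of -0.23 (adjusted p = 3.3e-06; adjusted p = 0.324 with an estimated correlation), among them the myosin light chain Mylpf (-0.54 ± 0.06) and skeletal actin Acta1 (-0.45 ± 0.08). Of 9 mesothelial and epithelial markers 7 fell, 8 adjusted over the list alone, with a median of -0.54 (adjusted p = 3.4e-06; adjusted p = 0.324 with an estimated correlation). Of 15 endothelial markers 6 fell and 1 rose, 10 and 1 adjusted over the list alone, with a median of -0.18 (adjusted p = 0.000226; adjusted p = 0.324 with an estimated correlation); Emcn fell by 0.26 (SE 0.05) and Flt1 rose by 0.20 ± 0.03.

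Glycolysis did not pass (adjusted p = 0.0605), but 5 of its 17 genes rose, among them the aldolases Aldoc (0.50 ± 0.07) and Aldoa (0.22 ± 0.04). The adipogenic transcription factors did not pass either (adjusted p = 0.595), with 4 of 18 rising and 2 falling. Mlxipl, Srebf1, which drives lipid synthesis (0.47 ± 0.08), and Pparg (0.37 ± 0.08) rose, and the differentiation inhibitor Id2 (-0.17 ± 0.04) fell. Preadipocyte and progenitor markers split, with 4 rising and 2 falling of 23 (adjusted p = 0.529). Clec11a (0.52 ± 0.09) and Dlk1 (0.22 ± 0.05) rose, and Dpp4 (-0.32 ± 0.05) fell. In insulin and AKT signalling 5 of 26 rose and 1 fell, Igfbp5 (-0.41 ± 0.04), with adjusted p = 0.529 for the list. The median and the mean had opposite signs in the insulin, the brown and beige, and the NRF2 lists.

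**Figure D3:**
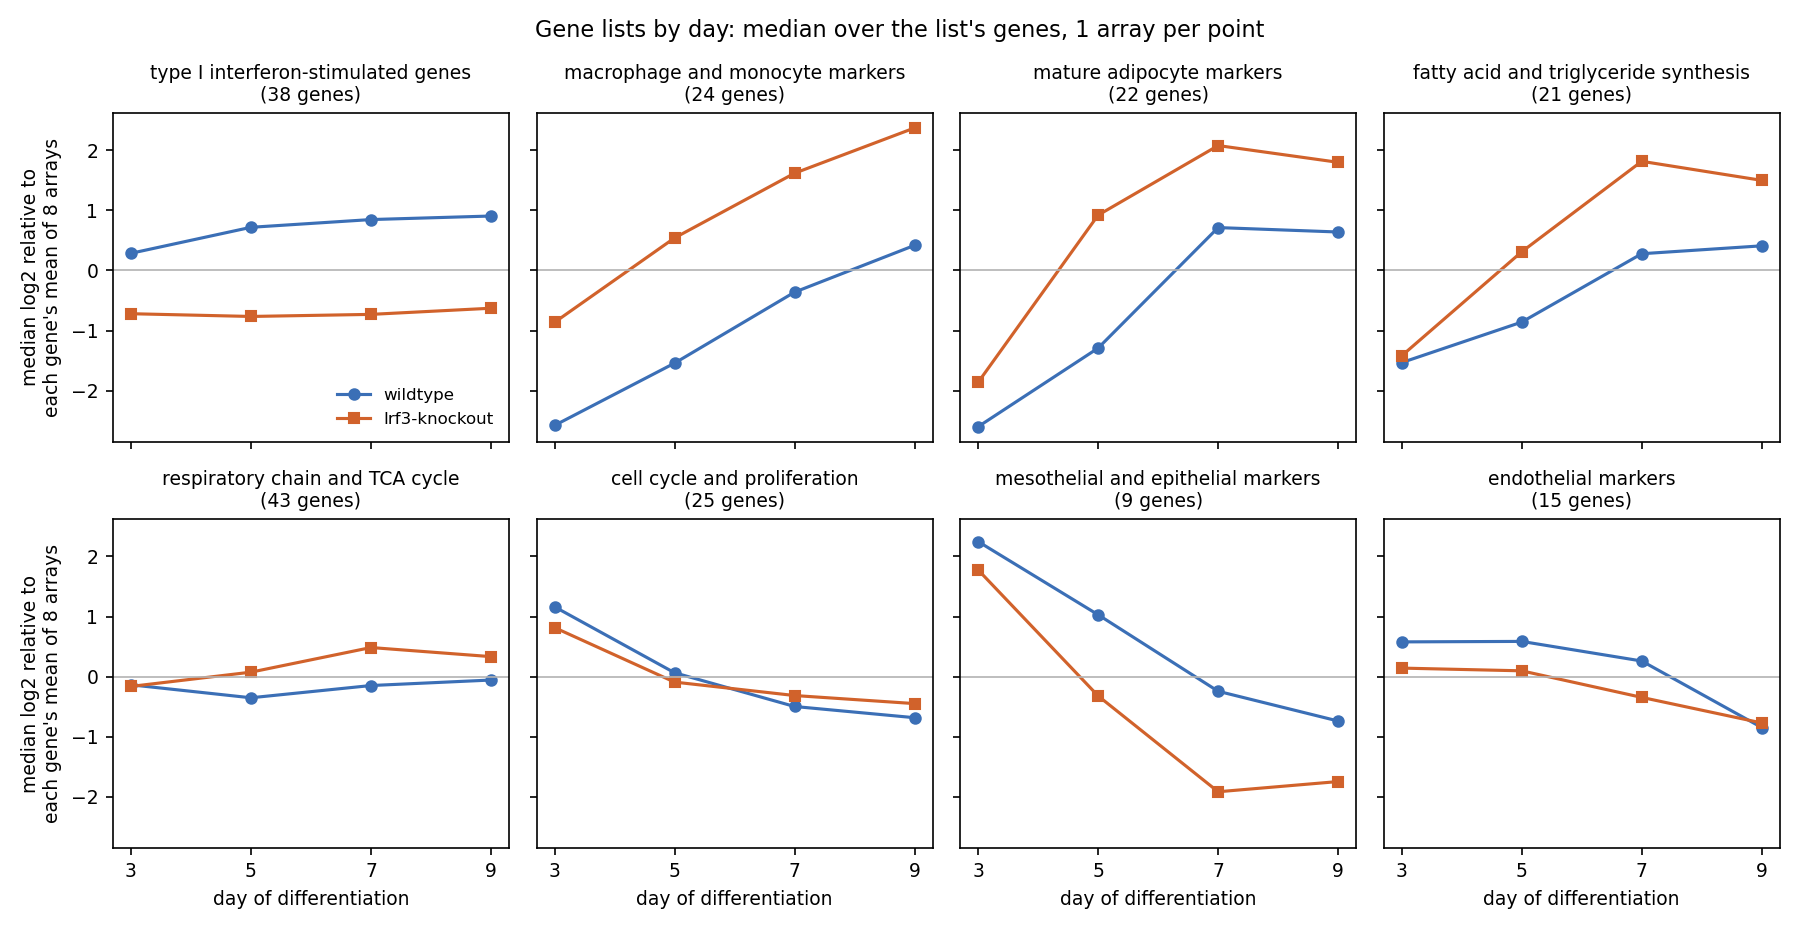
Median log2 intensity of 8 gene lists relative to each gene's mean of the 8 arrays (vertical axis) by day (horizontal axis), with 1 array per point. The macrophage list rose from each day to the next in both genotypes, the adipocyte list rose to day 7 and was slightly lower on day 9, and both lay higher in knockout on each day, and the interferon-stimulated list lay lower in knockout on each day.

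The courses of the genotypes were compared by the difference of their slopes. No single gene passed (limma, 0 of 9758; lowest adjusted p = 0.158), with 595 genes at an unadjusted p under 0.05. In the tests on simulated data 94 of 100 slope differences of 0.5 per day were called, but only 10 of 100 of 0.25. The lack of calls is therefore not evidence that the slopes are alike. None of the genes with the smallest p passed. Among them Lyve1, a hyaluronan receptor, had a slope of 0.20 per day in wildtype and 0.90 in knockout (difference 0.71 ± 0.09), and Fcrls, above background on 1 wildtype and 3 knockout arrays, a difference of 0.89 ± 0.12, Klhl6 of 0.51 ± 0.07, Smagp of 0.55 ± 0.06 and the endothelin receptor Ednrb of 0.42 ± 0.06. In the other direction, Cd300ld differed by -0.56 ± 0.07, although it was above background on 2 wildtype arrays and on no knockout array. In the same direction, Apoc1 differed by -0.70 ± 0.15, Prl2c3 by -0.39 ± 0.09, Brdt by -0.31 ± 0.06 and the prostaglandin receptor Ptger3 by -0.31 ± 0.06. Ednrb passed with a trended and robust prior, and Ednrb and Fcna, the latter named after its values were seen, without background correction. Of the 25 lists 8 passed camera, none of them with an estimated correlation or with fry; these 8 are given with the closing observations.

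**Figure D4:**
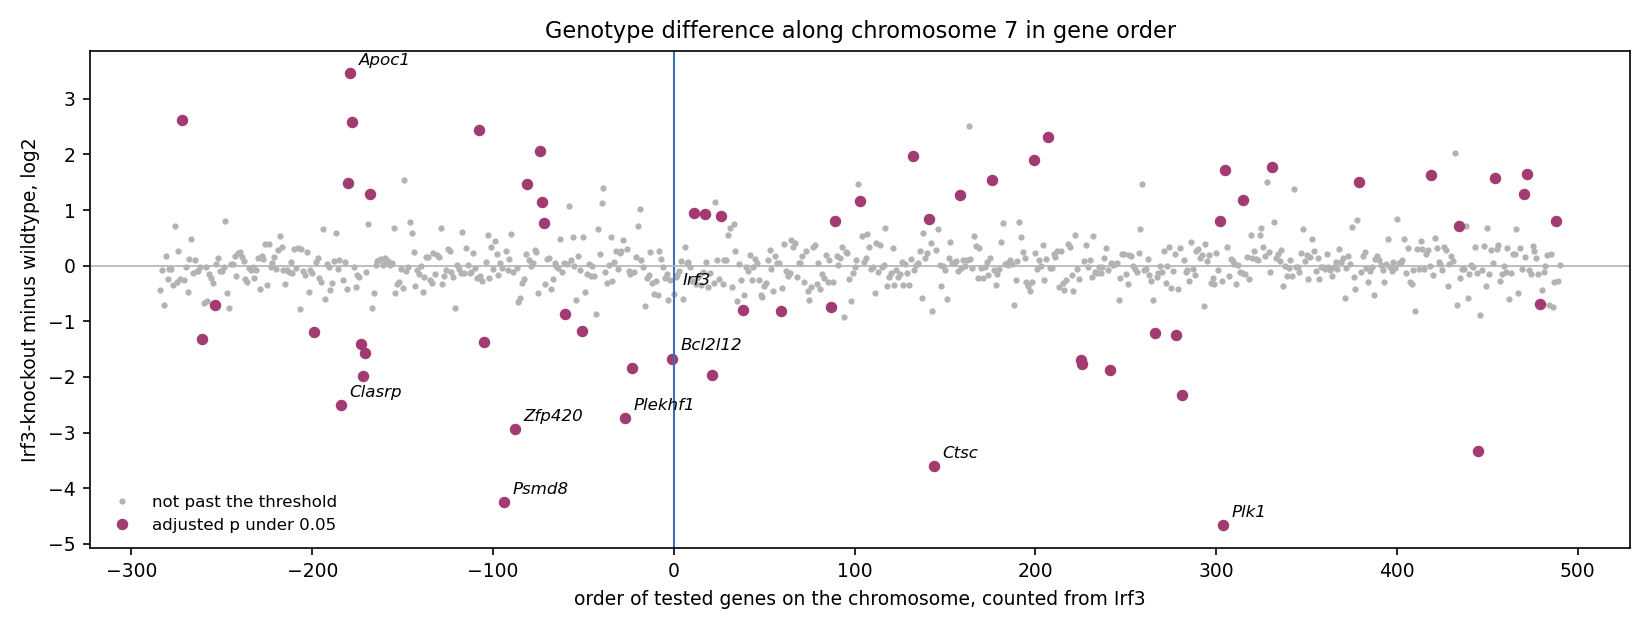
Log2 difference between knockout and wildtype (vertical axis, mean of 4 days) of the 775 tested genes of chromosome 7 in reference order counted from Irf3 (horizontal axis), with called genes in purple. Called genes are spread along the whole chromosome, in both directions, and Plk1, Psmd8, Ctsc and Apoc1 are among them.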

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

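The slopes of 8 gene lists differed between the genotypes by camera at the preset correlation; none of the 8 passed with an estimated correlation (adjusted p = 0.591 for 7 of them and 0.645 for fatty acid and triglyceride synthesis) or with fry. All values are medians of the differences in slope, knockout minus wildtype, in log2 per day, and each test was chosen before the data were examined. Type I interferon-stimulated genes differed by -0.10 (adjusted p = 5.2e-06), with median slopes of 0.13 in wildtype and 0.02 in knockout, and passed with each of the 8 arrays left out in turn. Interferon-gamma-type and antigen presentation genes differed by -0.078 (adjusted p = 0.0150), with slopes of 0.14 and 0.01, and did not pass without the wildtype array of day 5 (-0.054) or the knockout array of day 3 (-0.078) or 9 (-0.058). The respiratory chain and TCA cycle list differed by 0.072 (adjusted p = 2.1e-05), with 38 of 43 members above 0, and did not pass without the day 3 array of wildtype (0.026) or knockout (0.040). Cell cycle genes differed by 0.12 (adjusted p = 0.000107), with slopes of -0.30 and -0.20 and 23 of 25 members above 0, and did not pass without the wildtype array of day 3 (-0.046) or the knockout array of day 9 (0.028).

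Fatty acid and triglyceride synthesis differed by 0.072 (adjusted p = 0.0120), with 20 of 21 members above 0, and did not pass without the wildtype array of day 9 (-0.058), without the knockout array of day 3 (-0.14) or on the deposited processed values (0.050). Glycolysis differed by 0.072 (adjusted p = 0.0159), with 14 of 17 members above 0, and did not pass without the wildtype array of day 3 (0.097) or 9 (0.070), without the knockout array of day 3 (0.018) or on the deposited processed values (0.049). Red blood cell and mast cell markers differed by -0.15 (adjusted p = 0.0283), with 0 of 5 members above 0, and did not pass without the wildtype array of day 3 (-0.035), 5 (-0.17) or 9 (-0.25) or the knockout array of day 9 (-0.084), with no filter (-0.062), or on the deposited processed values (-0.14). Skeletal muscle markers differed by -0.10 (adjusted p = 0.0283), with 9 of 11 members below 0, and did not pass without the wildtype array of day 3 (-0.083), 5 (-0.13) or 9 (-0.15), without the knockout array of day 3 (0.0015) or on the deposited processed values (-0.12). Among 819 probes with no gene listed, which no comparison of genes used, 35 were called for genotype, 19 higher and 16 lower in knockout, and 18 were at least 2-fold apart in the same direction on all 4 days.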

How the results depend on the processing

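The macrophage covariate, the 2-fold count without each day and the processed values without genes at the floor were chosen after seeing the data. The cause of the changes below was not tested, except where stated. Genes called for genotype, 473 at first, were 366 to 648 under other normalizations, filters, probe choices and day as a number. They were 771 with a trended and robust prior, 115 with no day term, and 161 (without day 9) to 1082 (without day 3) with single days left out. On the submitters' processed values they were 93, of which 89 were shared with the 473, and 375, of which 352 were shared, once the genes at 20 on all 8 arrays were left out, so the drop comes with these constant genes. With the macrophage mean as a covariate limma called 0 genes, with 1089 at an unadjusted p under 0.05, 6 lists passed and 18 of 25 list medians changed sign. Genotype takes 98.1% of the within-day variance of that mean and the variance of the estimate rises 53.0-fold, so this model cannot part the 2. Without background correction 67 genes were 2-fold apart on all 4 days and 150, 301, 442 and 353 on days 3, 5, 7 and 9. With single days left out the 2-fold count was 155 to 340. Scaling to 1 median turned the day 3 split from 303 higher and 230 lower to 213 and 293.

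Genes called for the change with day, 1638 at first, were 187 in wildtype and 253 in knockout arrays alone, where fewer arrays are fitted, and 408 to 1662 with single arrays left out. Other settings gave 1117 to 1926. Genes called for the difference in slope were 2 without background correction and 1 with a trended and robust prior. Lists past the threshold with an estimated correlation were 0 for genotype, 0 for day and 0 for the difference in slope. With fry they were 8 for genotype and 0 for the difference in slope. On the processed values 4 lists passed for the difference in slope, and 4 (without wildtype day 3) to 11 (without knockout day 9) with single arrays left out. Medians of the slope difference changed sign when single arrays were left out and ranged from -0.046 to 0.22 for cell cycle genes, -0.14 to 0.46 for fatty acid and triglyceride synthesis, -0.41 (without knockout day 3, adjusted p = 1.0e-06) to 0.35 for mature adipocyte markers, -0.40 to 0.17 for mesothelial markers and -0.16 to 0.0015 for skeletal muscle markers. Of 156 called values of named genes, 33 kept their call under all 7 settings run on them; 70 lost it without day 3, 36 without day 5, 48 without day 7, 65 without day 9 and 75 on the processed values. None of these 156 changed direction. No slide is given, so a slide term was not run.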

Other observations

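The tests of the main cell type's share, of Irf3 loss against preparations, of an earlier course, of the whole culture's course, of the segment as the cause of all differences and of single probes were chosen after the results were seen, and so were the genes named in the next paragraph.

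Of the genes at least 2-fold apart on all 4 days, 114 belong to none of the interferon, macrophage and mature adipocyte lists. Members of the other lists remain among the 114. These include Lpin1 of fatty acid and triglyceride synthesis, Krt18 of the mesothelial and epithelial list, Cxcl5 of the NF-kB list and Plk1 of the cell cycle list. The daily differences of 64 of the 114 varied by less than 1 on the log2 scale, and those of the other genes, such as Apoc1 with 5.95 on day 3 and 1.85 on day 9, varied more. Rab6b, a GTPase of vesicle transport, fell by 2.09 with a standard deviation over the days of 0.07, and Paip1, which binds the poly(A)-binding protein, rose by 2.13 with 0.10. Psmd8 (-4.26) and Psmb5 (-1.59), subunits of the proteasome that were each read by 1 probe, fell. No list of proteasome subunits was tested, so these genes do not speak for the proteasome as a whole. Adar, an RNA-editing enzyme that interferon induces, fell by 1.25. Ccl6, a chemokine of myeloid cells (2.01), Alox5ap, which leukocytes need to make leukotrienes (2.13), and Pf4, platelet factor 4 (1.60), rose, as did Bmp4, which commits precursors to the fat lineage (2.37).

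The deposited matrix of processed values holds 20 on all 8 arrays for 11109 probes, and 676 of these had a detection p under 0.05 on at least 2 arrays. None of the 676 had one on the wildtype array of day 3, where the lowest was 0.160. The 447 tested genes concerned include 130 called for the change with day, all 130 rising. The raw signal of Thrsp ran from 111.1 on wildtype day 3 to 15309.4, that of Orm1 from 121.8 to 10446.6, that of Adig from 117.1 to 8956.4 and that of Cidec from 98.3 to 4912.4, whereas the matrix holds 20 throughout. Of the sex markers, Xist was above background on all 8 arrays, Eif2s3y and Kdm5d on 0 and Uty on 3.

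Macrophage and monocyte markers were higher in the knockout cultures by a median of 1.77. A lower share of the main cell type would raise every other cell type alike only if their proportions to each other stayed the same. The endothelial list at -0.40 and the mesothelial and epithelial list at -1.20 argue against that form alone. These medians were already known when the test was set. Macrophages in the place of the main cell type could leave these lists lower too. The test therefore does not decide on the share of the main cell type. The skeletal muscle list, in contrast, stood at 0.42, and the endothelial list at only -0.12 on day 9. A larger share of macrophages may account for the pattern, since another list of leukocyte and macrophage genes, with 24 of 30 measured, had a median of 1.15 with 23 members above 0. Of the brightest macrophage genes Lyz2 stood at 13.07 in wildtype and 14.29 in knockout, Lgals3 at 14.27 and 14.32, neither called, and Laptm5 at 10.86 and 12.79. An effect of Irf3 loss on macrophages or their number and a difference between cell preparations cannot be told apart, since there was 1 array per genotype and day.

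For the mature adipocyte markers, which were higher in the knockout cultures, RNA of macrophages is argued against by the 14 of 22 members that macrophages do not also express, all 14 above 0 with a median of 1.56. A course earlier by 2 days in the culture as a whole is argued against by the cell cycle list, which falls with day but stood at -0.03 at matched days and at 0.58 against the wildtype array taken 2 days later, with 24 of 25 members above 0. A course of the fat cells earlier by exactly 2 days would leave pairs 2 days apart alike, and a constant offset would leave matched days alike. The adipocyte list's medians in the pairs 2 days apart were -0.44, 0.29 and 1.45, and those at matched days 0.37, 2.45 and 1.33, so that the range over the pairs was 0.909 of that at matched days. Neither simple form matched, and whether an earlier course of another kind took part cannot be told from these arrays.

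Differences of at least 2-fold on every day outside these lists may have a source other than the response to Irf3 loss. A chromosome segment around Irf3 that differs between the strains of the cultures is a candidate for some of them. The tests that follow count all tested genes, members of the lists included, and treat neighbouring genes as independent. Of the 100 tested genes on each side 19 of 200 were called, 2.08 times the share on other chromosomes (two-sided Fisher's exact p = 0.00329). Among the 25 protein-coding genes on each side, 23 were tested and 2 called (exact p = 0.285). On all of chromosome 7 25 of 774 were 2-fold apart on all days, 3.23% against 1.38% elsewhere (exact p = 0.000319), the highest share of any chromosome. Near Irf3 only 4 of 200 were (exact p = 0.363), and chromosome 14 had a higher share of called genes, 8.07% against 7.88%. Outside the lists 20 of the 114 genes lie on chromosome 7, and 3 are among the 200 around Irf3. The 25 include members of the lists. The 20 include genes that rose beside the macrophage markers, such as Folr2 and Gmfg, or fell beside the interferon-stimulated genes, such as Trim30d. The excess on chromosome 7 therefore does not show how many of its genes differ through a segment. A segment as the cause of all of them is argued against by the 94 of 114 genes on other chromosomes. The 94 include genes of macrophages or induced by interferon that the lists do not hold, such as Trem2 and Adar. They also include members of other tested lists, such as Krt18 and Lpin1. The count of 94 therefore does not show how many differences have another source. Single probes that respond to a sequence variant or isoform could be examined in the 21 of 114 genes with another probe. The difference of that probe had a median ratio to the first of 0.847, with 14 at 0.7 or above. This argues against single probes as the source in those 14. The 14 include Adar (1.28), which interferon induces, so they need not stand for the other genes. Single probes stay open for the 5 under 0.5, among them Pxylp1, Esd and Noct. For the 93 genes with 1 probe this cannot be told. Psmd8, Psmb5, Plk1, Lars2, Prkag2, Nudt6 and Csn3 are among them. Other strain differences and differences between the preparations stay open too, since neither strain nor animals are given in the sources used here.

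The genotype labels were also swapped within days, which gives 8 arrangements, too few for a share under 0.05. The real one, the 1 arrangement with so many, gave 473 called genes, and the highest of the others 0. For genes at least 2-fold apart on all 4 days the real one gave 149 and the highest other 1. With no day term the 8 arrays can be split into 4 and 4 in 35 ways. The real split gave 115 called genes and the highest other 2, so that 1 split, the real one, gave as many. These splits ignore the shared days and do not speak to a difference between cultures, and the arrangements that keep the days are too few, so chance is not taken as excluded.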
